A study of Mus musculus with 24 samples.

How the data were processed

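Total RNA from the proximal colon of 24 mice was hybridised to 24 Affymetrix arrays, 1 mouse per array. Per the labels' protocols, the mice had been germ-free before gavage, the tissue was snap-frozen, RNA was extracted with an RNeasy kit, and biotinylated cRNA was prepared from 10 ug of total RNA. Each sample was put into 1 of 8 groups of 3 by the donor community in its label. The deposited table holds an intensity for each of 45101 probe sets on each array, on a linear scale, and per the submitters' processing notes these signals come from MAS5. The version of that software is not given in the sources used here. MAS5 summarises each probe set within its own array and scales every array by 1 factor. In the deposited values the mean after trimming 2% at each end was 500 on each array, which fixes the mean level of every array, so a change shared by all genes could not be seen. Median signals ran from 109.5 to 126.6 with a median of 118.4 over arrays. Signals of weak probe sets are noisy in MAS5, which the filter and the added constant below were meant to limit.

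Probe sets were named through the platform's annotation table and the mouse gene table of assembly GRCm38.p6, which was used for names only, and no genome coordinates are given. Of the 45101 probe sets, 34945 had 1 gene, 932 had several, 9160 were not listed in the annotation and 64 were array controls. Of those with 1 gene, 34741 were matched to the gene table by gene identifier and 0 symbols changed. For each of the 18193 genes the probe set with the highest mean signal over the 24 arrays was used. Where a gene had several probe sets called in a comparison they had the same sign, except for 1 gene in the termite hindgut comparison. Genes were tested if that mean was at or above 120.4, the median of the means of all probe sets other than controls, which left 11456 genes. Probe sets of immunoglobulin segments and other multigene families can bind related transcripts.

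Values were analysed as log2(signal + 50) in R 4.3.3 with limma 3.58.1. A linear model with 8 group means was fitted to all 24 arrays (16 residual degrees of freedom), with eBayes and a mean-variance trend. Each of 7 communities was compared with mouse cecum by limma's two-sided moderated test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 without a minimum fold. A moderated F-test over the 7 contrasts asked whether any group differed. Gut-derived and non-gut communities were compared, 4 against 4, on the 8 group means. Of 44 gene lists (pathways, epithelial cell types and other cell types of the gut), 39 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01, adjusted over the 273 list tests of the 7 comparisons, and again with a correlation estimated for each list. Counts adjusted over a list alone use only the genes of that list.

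Genes were named by a rule. In each comparison it takes, among called genes whose 3 values do not overlap the 3 mouse cecum values, the 6 largest rises and the 6 largest falls. It adds up to 4 called members with the smallest adjusted p from each list that is called or has 3 or more called genes, the 10 genes with the smallest p of the F-test, the 3 smallest p in each direction where nothing passes, and a set of genes known to respond to microbes. Predicted genes without a standard symbol were passed over. The groups, tests, lists, naming rule and all alternatives except the fit with the Hox score were set before the data were examined. The Hox score, the first principal component of the 17 tested Hox genes, was added afterwards as a covariate.

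The alternatives were a constant of 1 or 200, quantile normalization, scaling of each array to the same median over tested genes, no filter, a stricter filter at the 70th percentile (382.2), all probe sets, a robust eBayes fit, a fit of only the groups compared, the replicate number as a block, each array left out in turn, and for the gut-derived comparison each community left out in turn and the 24 mice as units. With an array left out, its group has fewer arrays and relies on the pooled spread. The gene test was checked on simulated data made from each gene's mean over all 24 arrays and its spread within the 8 groups. In the zebrafish gut group 200 of 11456 genes were changed. The test recovered 66% of the genes changed by 0.5 on the log2 scale and 98% of those changed by 1, with 7 false calls (3.7%). The simulated genes were independent, so this share is not shown for correlated genes. Correlations of deviations from group means used 100000 permutations within groups, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.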

Results

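Gene expression was measured in the proximal colon of 24 male C57BL/6 mice that had been raised without microbes and were then gavaged with a microbial community from 1 of 8 sources. The donor communities came from mouse cecum, zebrafish gut, a microbial mat, skin, human feces, tongue, soil and termite hindgut, and each went to 3 mice, which the labels call biological replicates. The mice were 12 to 16 weeks old, ate the same diet in plastic isolators and were killed about 28 days after the gavage. RNA of each mouse went to its own Affymetrix array. How the isolators were shared among the groups is not given in the sources used here, so an isolator and a community could not be separated. The mouse cecum community, which comes from the recipients' own species, served as the reference, and germ-free colons were not analysed here.

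The 24 arrays had median signals and actin ratios in narrow ranges, while signals of array controls varied more, and some measures differed by group. Their median signals lay between 109.5 and 126.6 on a table scaled by the submitters to the same trimmed mean, and the ratio of 3' to 5' actin signal ran from 1.247 to 1.424. Mouse cecum arrays had medians of 113.4 to 114.7, below every other array except termite hindgut replicate 1. Their actin ratios of 1.348 to 1.419 lay above those of all zebrafish gut, tongue and soil arrays. Soil replicate 2 had the highest signals of the array controls BioB, 410.5 against a median of 242.6, and Cre, 19578.3 against 12870. Correlations of log2 signal across genes were 0.9729 to 0.9926 within groups and 0.9509 to 0.9903 between groups, and 21 of the 24 arrays had their closest array in their own group. No pair of arrays held identical values. With 3 mice per group the number of arrays limits the precision, and the median standard error of a log2 difference was 0.114.

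The donor community was associated with broad differences in the colon transcriptome. Ces2a, a carboxylesterase that hydrolyses drugs and lipids, had the smallest p in the test over all 8 groups, with a signal of 8600 ± 211 (SD, n = 3) in mouse cecum recipients and 757 ± 327 in skin recipients (adjusted p = 2.64e-09). The carbonyl reductase Cbr3 came next, at 3860 ± 347 in mouse cecum recipients and 1160 ± 182 in termite hindgut recipients (adjusted p = 3.55e-09). Of the 10 genes with the smallest p, 4 belong to the circadian clock or its direct output, namely Npas2, Dbp, Tef and Ciart. The other 6 were Ces2a, Cbr3, the amino acid transporter subunit Slc7a9, the dipeptidase Cndp2, the phosphate transporter Slc34a2 and the small proline-rich protein Sprr1a. Slc7a9 ranged from 410 ± 102 in human feces recipients to 2350 ± 192 in termite hindgut recipients. In all, 2342 of the 11456 genes tested (20.4%) differed among the 8 groups by limma's moderated F-test. Against mouse cecum, between 414 genes (microbial mat) and 1180 genes (termite hindgut) passed an adjusted p of 0.05, and in each comparison between 21.5% and 29.1% of all genes tested had group values that did not overlap, where chance gives 10%. Levels below are deposited signals as mean ± SD of 3 mice, and differences are on the log2(signal + 50) scale with their SE, which understates changes of weakly expressed genes. Where leaving out 1 array moved a count of called genes by more than 1.5 times, the value without it is given beside that count.

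**Figure D1:**
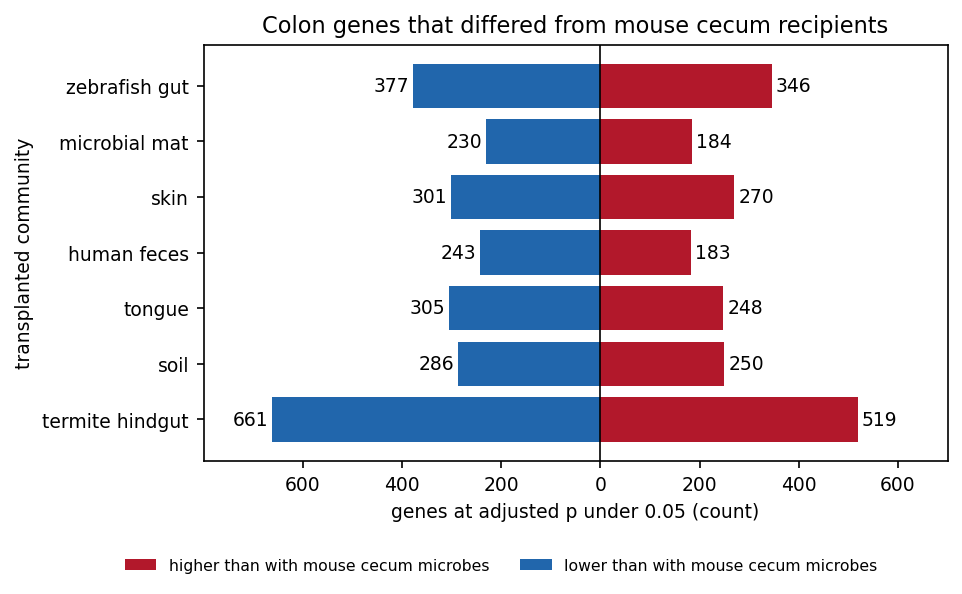
Genes higher (red bars, to the right) and lower (blue bars, to the left) than in mouse cecum recipients at an adjusted p under 0.05, for the 7 other communities. The totals run from 414 genes for the microbial mat to 1180 for the termite hindgut.

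Genes that mark position along the gut also differed between mice. Hoxb13, a Hox gene of the most distal gut, had a signal of 3.73 ± 3.06 in mouse cecum recipients and 2280 ± 1440 in termite hindgut recipients (log2 difference 5.15 ± 1.22, adjusted p = 0.0102). That call was lost without termite hindgut replicate 2 (4.715, adjusted p = 0.059), and the test of the same gene with a Hox score in the model gave -0.311 (adjusted p = 0.837). The score was set after the data had been seen, as the first principal component of the 17 Hox genes tested, which held 78.6% of their variance and was dominated by Hoxb13 (loading 0.836). It was low in all 3 mouse cecum recipients (-1.13, -1.08 and -1.22) and zebrafish gut recipients (-1.15, -1.13 and -0.89). Termite hindgut recipients had 0.70, 1.56 and 1.32, human feces recipients 0.64, -0.13 and 1.13, and tongue recipients -0.04, 0.51 and 1.94. The remaining mice scattered within their groups, at -0.74, 0.52 and -0.32 for the microbial mat, -1.04, -0.61 and 1.19 for skin, and -0.24, 0.94 and -0.72 for soil. Among genes singled out after their values were seen, Mptx1, a mucosal pentraxin, Tgm3, a transglutaminase, and Insl5, a hormone of colonic L cells, had their lowest group means in mouse cecum recipients, at 162 ± 101, 104 ± 21.7 and 222 ± 17.4. The carbonic anhydrase Car4 (10300 ± 609, against 9590 to 18800 in the other groups) and the water channel Aqp8 (3830 ± 1500, against 2010 to 6410) did not. A fit with the score as a covariate was added for every comparison. It takes its slope from the spread within groups and extrapolates where a group's scores do not overlap those of mouse cecum.

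**Figure D2:**
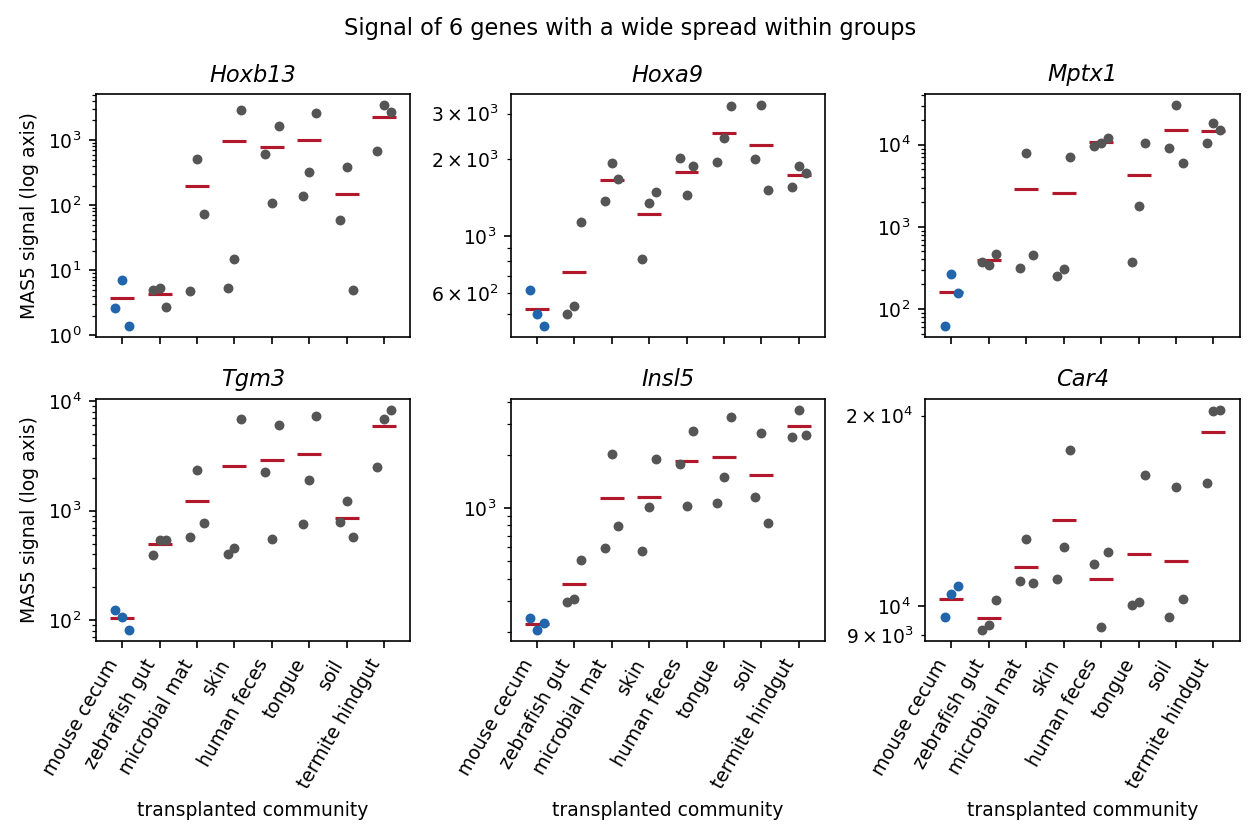
Deposited signals (log axis) of Hoxb13, Hoxa9, Mptx1, Tgm3, Insl5 and Car4 in each of the 24 mice, by community, with mouse cecum recipients in blue and group means as red lines. Hoxb13 averaged 3.73 in mouse cecum recipients and 2280 in termite hindgut recipients, and values scatter widely within several groups.

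In zebrafish gut recipients, clock genes were among the genes that differed by the largest amounts from mouse cecum recipients. Dbp, a transcription factor under direct clock control, rose 11.2-fold from 360 ± 15.7 to 4020 ± 86.8 (log2 difference 3.31 ± 0.21, adjusted p = 1.62e-09). The period genes Per2 (147 ± 52 to 687 ± 90) and Per3 (131 ± 23.9 to 579 ± 144), the output factor Tef (775 ± 57.3 to 2730 ± 274) and the repressor Ciart (89.7 ± 3.67 to 401 ± 41.6) rose with it. In all, 8 of 9 tested clock genes driven through E-boxes, the DNA element bound by Bmal1 and its partners, rose (9 adjusted over the list alone). Their median was 1.69 (camera adjusted p = 2.11e-20, and adjusted p = 0.000916 with an estimated correlation). Clock genes that peak with Bmal1 moved the other way, with 3 of 5 lower (3 adjusted over the list alone) and a median of -1.14 (adjusted p = 7.16e-08, and 0.00238 with an estimated correlation). Arntl, which encodes Bmal1, fell from 838 ± 80.6 to 355 ± 59.1, its partner Npas2 from 789 ± 103 to 230 ± 13.8, and the repressor Nfil3 from 383 ± 55.9 to 62.3 ± 5.55. Proliferation genes were lower too. Of 20 cell cycle genes, 14 fell (17 adjusted over the list alone), including the topoisomerase Top2a (2650 ± 215 to 1490 ± 78.3, log2 -0.81 ± 0.09, adjusted p = 1.57e-05) and the proliferation marker Mki67 (2610 ± 137 to 1800 ± 144). The cell cycle median was -0.47 (adjusted p = 1.45e-15, but adjusted p = 0.0839 with an estimated correlation).

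Other genes that fell in zebrafish gut recipients included Ces2a (8600 ± 211 to 1250 ± 27.6, log2 -2.74 ± 0.23), the manganese exporter Slc30a10 (408 ± 28.4 to 68.3 ± 13.8) and Sprr1a (1150 ± 251 to 297 ± 19.9). Of 20 tested genes of xenobiotic metabolism, 8 fell and 2 rose (8 and 3 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.0124, and adjusted p = 0.237 with an estimated correlation). The 2 that rose were Cyp2d26, to 5330 ± 191 from 1670 ± 28.4, and Cyp1a1, the classical target of the aryl hydrocarbon receptor, to 796 ± 130 from 331 ± 48.9. The acute-phase proteins Saa1 and Saa2 rose, Saa1 from 8080 ± 1250 to 20000 ± 1740 (log2 1.31 ± 0.16, adjusted p = 2.59e-05). Among macrophage and dendritic cell genes, 2 of 16 fell (8 adjusted over the list alone), with a median of -0.32 (adjusted p = 5.12e-05, and adjusted p = 0.359 with an estimated correlation). Lists of other cell types were called lower beside them. Fibroblast genes fell in 4 of 16 cases (5 adjusted over the list alone), with a median of -0.21 (adjusted p = 6.38e-05, and adjusted p = 0.359 with an estimated correlation). Endothelial genes fell in 1 of 12 cases (4 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.0031, and adjusted p = 0.139 with an estimated correlation), or -0.107 without zebrafish gut replicate 1. The plasma cell list had a median of -0.33 (adjusted p = 0.00141, and adjusted p = 0.446 with an estimated correlation), with 0 of 13 genes past limma's threshold (0 adjusted over the list alone) and 4 at an unadjusted p under 0.05. Small intestinal enterocyte genes rose in 2 of 9 cases (3 adjusted over the list alone), with a median of 0.56 (adjusted p = 0.0131, and adjusted p = 0.23 with an estimated correlation), or 0.356 without mouse cecum replicate 3. In total 346 genes were higher and 377 lower by limma's test (723 genes, 6.31% of those tested), or 286 higher and 470 lower with each array scaled to the same median. Of 39 lists, 16 were called, 2 up and 14 down. The gene count was 271, 303 and 471 without zebrafish gut replicates 1, 2 and 3, and 350 and 450 without mouse cecum replicates 2 and 3.

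**Figure D3:**
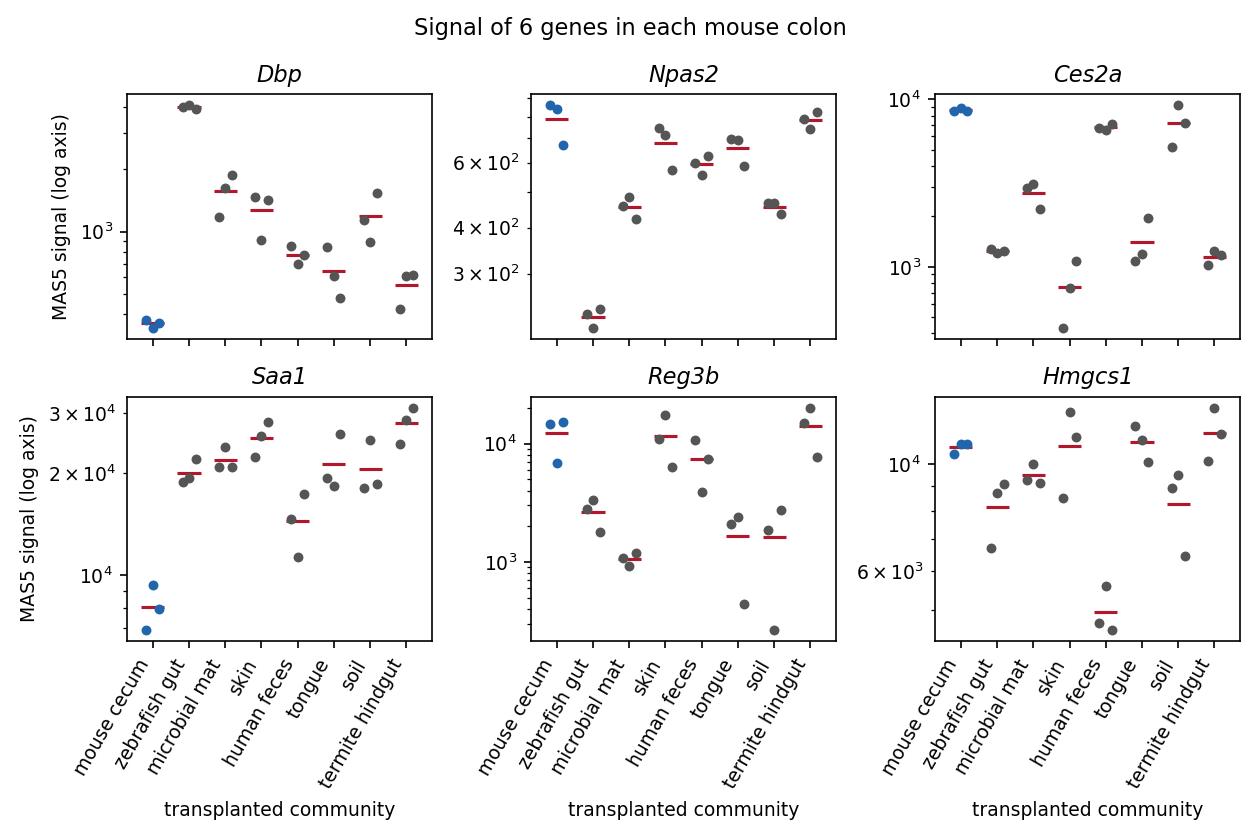
Deposited signals (log axis) of Dbp, Npas2, Ces2a, Saa1, Reg3b and Hmgcs1 in each of the 24 mice, by community, with mouse cecum recipients in blue and group means as red lines. Dbp lies at 4020 ± 86.8 in zebrafish gut recipients and 360 ± 15.7 in mouse cecum recipients, and Ces2a lies at 757 ± 327 in skin recipients and 8600 ± 211 in mouse cecum recipients.

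Recipients of the microbial mat community had lower transcripts of antibody-secreting cells and of a major antimicrobial lectin. Of 13 plasma cell genes, 8 fell (11 adjusted over the list alone). Jchain, which joins polymeric antibodies, fell from 18500 ± 2150 to 6320 ± 533 (log2 -1.54 ± 0.22, adjusted p = 0.000373), Igha, the IgA heavy chain, from 24300 ± 2330 to 13400 ± 889, and the B-lineage coactivator Pou2af1 from 382 ± 74.1 to 119 ± 9.47. The plasma cell median was -0.86 (adjusted p = 3.86e-11, and adjusted p = 0.0547 with an estimated correlation). Reg3b, an antimicrobial C-type lectin, fell from 12200 ± 4590 to 1070 ± 135 (log2 -3.38 ± 0.65, adjusted p = 0.00426). The antigen-presenting MHC class II list had 3 of 8 genes lower (5 adjusted over the list alone) and a median of -0.63 (adjusted p = 0.000277, and adjusted p = 0.446 with an estimated correlation). Macrophage and dendritic cell genes fell in 6 of 16 cases (11 adjusted over the list alone), among them the complement components C1qa (2070 ± 123 to 1350 ± 43.4) and C1qc (1310 ± 51.5 to 782 ± 53.8), with a median of -0.51 (adjusted p = 7.3e-10, and adjusted p = 0.113 with an estimated correlation). Fibroblast genes fell in 1 of 16 cases (2 adjusted over the list alone, median -0.18, adjusted p = 0.00111, and adjusted p = 0.458 with an estimated correlation). Endothelial genes fell in 1 of 12 cases (3 adjusted over the list alone, median -0.11, adjusted p = 0.0229, and adjusted p = 0.3 with an estimated correlation). This call was lost without microbial mat replicate 1 (-0.069, adjusted p = 0.0565) or mouse cecum replicate 3 (adjusted p = 0.0819). Smooth muscle genes rose in 1 of 16 cases (1 adjusted over the list alone, median 0.14, adjusted p = 0.0131, and adjusted p = 0.673 with an estimated correlation). That call was lost without mouse cecum replicate 1 (adjusted p = 0.124) or 3 (0.085, adjusted p = 0.128). With the Hox score in the model the call was lost although the median was 0.161 (adjusted p = 0.0706), and the median was 0.228 without mouse cecum replicate 2. The B cell list had a median of -0.65 (adjusted p = 0.0131, and adjusted p = 0.671 with an estimated correlation), with 0 of 9 genes past limma's threshold (2 adjusted over the list alone) and 3 at an unadjusted p under 0.05, and its call was lost without mouse cecum replicate 3 (adjusted p = 0.0817). The list of cytotoxic and intraepithelial lymphocytes had a median of -0.27 (adjusted p = 0.0147, and adjusted p = 0.473 with an estimated correlation), with 0 of 7 genes past limma's threshold (2 adjusted over the list alone) and 2 at an unadjusted p under 0.05. Its call was lost without mouse cecum replicate 1 (adjusted p = 0.0801), and its median was -0.445 without mouse cecum replicate 2. Immunoglobulin variable segments such as Igkv9-120 (6490 ± 2350 to 955 ± 726) also fell, but their probe sets may bind related segments and their identity is uncertain.

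Clock genes moved in the mat recipients as well. Of the 9 E-box genes, 6 rose (7 adjusted over the list alone), with Dbp at 1560 ± 361 and a median of 0.78 (adjusted p = 5.2e-10, and 0.0138 with an estimated correlation). The Bmal1-phase list had 2 of 5 genes lower (4 adjusted over the list alone), including Npas2 at 454 ± 31.5, and a median of -0.62 (adjusted p = 0.000609, and 0.0335 with an estimated correlation). Enterocyte genes typical of the small intestine were higher, with 4 of 9 past the threshold (7 adjusted over the list alone) and a median of 0.71 (adjusted p = 3.2e-05, and 0.0335 with an estimated correlation). Among them were the brush-border enzymes Alpi (1320 ± 63.7 to 2770 ± 266) and Enpep (1720 ± 226 to 3970 ± 501). The amino acid transporter Slc6a20a rose from 157 ± 19.2 to 582 ± 12.6 and Hoxa9 from 520 ± 87.2 to 1660 ± 277, while the calcium-binding protein S100g fell from 1290 ± 485 to 188 ± 101. In total 184 genes were higher and 230 lower (414 genes, 3.61% of those tested). Of 39 lists, 18 were called, 3 up and 15 down (11 without mouse cecum replicate 3). Without microbial mat replicates 1, 2 and 3 the count was 208, 163 and 193, and without mouse cecum replicates 2 and 3 it was 233 and 218.

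In skin recipients, genes of detoxification fell and genes typical of small intestinal enterocytes rose. Ces2a fell from 8600 ± 211 to 757 ± 327 (log2 -3.51 ± 0.23, adjusted p = 4.22e-09). Cbr3 fell from 3860 ± 347 to 1320 ± 116, the quinone oxidoreductase Nqo1 from 1340 ± 5.98 to 663 ± 72, the glutathione transferase Gstm3 from 4140 ± 477 to 1740 ± 195 and the aldo-keto reductase Akr1b8 from 5150 ± 631 to 2260 ± 490. In the xenobiotic list 8 of 20 genes fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -0.20 (adjusted p = 3.49e-05, and 0.0351 with an estimated correlation). Higher transcripts included Slc7a9 (581 ± 42.8 to 1730 ± 279), Slc34a2 (450 ± 27.4 to 1120 ± 109), Enpep (1720 ± 226 to 4770 ± 499), Fabp6, the ileal bile acid-binding protein (222 ± 62.9 to 519 ± 145), and the apolipoprotein Apoa1 (27.6 ± 21 to 223 ± 63.8). The small intestinal enterocyte list rose in 2 of 9 genes (6 adjusted over the list alone), with a median of 0.65 (adjusted p = 9.84e-05, and 0.0415 with an estimated correlation). Arg2, the mitochondrial arginase, fell from 1380 ± 76.5 to 317 ± 30 (log2 -1.97 ± 0.24, adjusted p = 2.62e-05), S100g from 1290 ± 485 to 107 ± 76.5, and Sprr1a from 1150 ± 251 to 217 ± 64.2.

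Macrophage and dendritic cell genes were lower in skin recipients, with 9 of 16 past the threshold (9 adjusted over the list alone). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 3110 ± 136 to 1950 ± 134 (log2 -0.66 ± 0.11, adjusted p = 0.000617) and C1qc from 1310 ± 51.5 to 736 ± 60.2. The median was -0.54 (adjusted p = 6.31e-10, and adjusted p = 0.113 with an estimated correlation). Lists of other cell types moved in the same mice. Fibroblast genes fell in 2 of 16 cases (7 adjusted over the list alone, median -0.27, adjusted p = 0.000115, and adjusted p = 0.384 with an estimated correlation) and endothelial genes in 2 of 12 (4 adjusted over the list alone, median -0.17, adjusted p = 0.00151, and 0.111 with the estimate). Plasma cell genes fell in 1 of 13 cases (2 adjusted over the list alone, median -0.37, adjusted p = 0.00947, and adjusted p = 0.493 with an estimated correlation). The list call was lost without skin replicate 1 (adjusted p = 0.0712). Smooth muscle genes rose in 1 of 16 cases (1 adjusted over the list alone, median 0.21, adjusted p = 0.00267, and adjusted p = 0.578 with an estimated correlation). This list call was lost without mouse cecum replicate 3 (0.098, adjusted p = 0.0551). Mature colonocyte genes rose in 1 of 17 cases (2 adjusted over the list alone, median 0.20, adjusted p = 0.0374, and adjusted p = 0.515 with an estimated correlation). That call was lost without skin replicates 2 and 3 (adjusted p = 0.15 and 0.196) or mouse cecum replicate 1 (0.255), and with the Hox score in the model (0.032, adjusted p = 0.368). E-box clock genes rose in 5 of 9 cases (6 adjusted over the list alone), with Dbp at 1270 ± 312 and a median of 0.54 (adjusted p = 3.74e-06, and 0.0426 with an estimated correlation). Saa1 rose to 25400 ± 2930 and Saa2 to 1280 ± 194, from 8080 ± 1250 and 357 ± 30. In total 270 genes were higher and 301 lower (571 genes, 4.98% of those tested). Of 39 lists, 13 were called, 5 up and 8 down. The gene count was 372 and 296 without skin replicates 2 and 3, and 256 and 319 without mouse cecum replicates 2 and 3.

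Human feces recipients had lower transcripts of cholesterol synthesis than mouse cecum recipients. Of 18 genes of cholesterol biosynthesis and its regulator SREBP2, 10 fell (16 adjusted over the list alone). Hmgcs1, an early enzyme of the pathway, fell from 10800 ± 291 to 4950 ± 570 (log2 -1.13 ± 0.15, adjusted p = 0.000296). The squalene synthase Fdft1 fell from 3880 ± 426 to 1670 ± 288, Hsd17b7 from 807 ± 34.2 to 420 ± 53.6, and Insig1, a sterol-responsive regulator, from 1890 ± 65.6 to 692 ± 14.5. The list had a median of -0.49 (adjusted p = 2.93e-15, and adjusted p = 0.111 with an estimated correlation). Fatty acid synthesis and lipid storage genes fell in 4 of 17 cases (8 adjusted over the list alone), with a median of -0.28 (adjusted p = 2.51e-05, and adjusted p = 0.188 with an estimated correlation). Camera called the same list lower in zebrafish gut, skin, tongue and soil recipients too, but not with an estimated correlation. In skin recipients its median was -0.139 without mouse cecum replicate 1 and -0.361 without skin replicate 2. In soil recipients it was -0.11 and -0.296 without mouse cecum replicates 1 and 3. The zebrafish gut call was lost without mouse cecum replicate 1 (adjusted p = 0.0626) or zebrafish gut replicates 1 and 3 (0.0577 and 0.144). The tongue call was lost with the Hox score in the model (-0.075, adjusted p = 0.249). Cell cycle genes fell in 10 of 20 cases (17 adjusted over the list alone), with a median of -0.39 (adjusted p = 1.54e-13, and adjusted p = 0.111 with an estimated correlation).

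The chemokine Ccl8 fell in human feces recipients from 1230 ± 154 to 359 ± 92.1 (log2 -1.66 ± 0.19, adjusted p = 9.12e-05). Macrophage and dendritic cell genes fell in 8 of 16 cases (11 adjusted over the list alone), C1qc to 826 ± 87.3 from 1310 ± 51.5, with a median of -0.44 (adjusted p = 4.95e-09, and adjusted p = 0.139 with an estimated correlation). The list of enteric neurons and glia was called higher, with a median of 0.21 (adjusted p = 0.0248, and adjusted p = 0.531 with an estimated correlation), 0 of 13 genes past limma's threshold (3 higher and 1 lower adjusted over the list alone) and 5 at an unadjusted p under 0.05. That call was lost without human feces replicate 2 (adjusted p = 0.0729) or mouse cecum replicate 3 (0.059, adjusted p = 0.541). The tuft cell list had a median of 0.37 (adjusted p = 0.0124, and adjusted p = 0.486 with an estimated correlation), with 0 of 7 genes past limma's threshold (0 adjusted over the list alone) and 4 at an unadjusted p under 0.05. The median was 0.566 without mouse cecum replicate 2, and the call was lost without mouse cecum replicate 1 (0.129, adjusted p = 0.457). The crypt base stem cell list had a median of 0.17 (adjusted p = 0.0344, and adjusted p = 0.384 with an estimated correlation), with 0 of 14 genes past limma's threshold (1 adjusted over the list alone) and 4 at an unadjusted p under 0.05. Its call was lost without human feces replicate 3 (adjusted p = 0.19), without mouse cecum replicates 1 and 3 (0.0626 and 0.0657) and with the Hox score in the model (0.11). The xenobiotic list fell in 4 of 20 cases (9 adjusted over the list alone), with Gstm3 at 2420 ± 140, and its median of -0.32 held with an estimated correlation (adjusted p = 1.19e-06, and 0.0239 with the estimate). Of the E-box clock genes, 2 of 9 rose (4 adjusted over the list alone), Per2 to 363 ± 20.4 and Dbp to 773 ± 78.7, with a median of 0.23 (adjusted p = 0.0016, and adjusted p = 0.188 with an estimated correlation), or 0.401 without human feces replicate 2. Insl5 rose from 222 ± 17.4 to 1840 ± 854 (log2 2.69 ± 0.47, adjusted p = 0.00338). Mptx1 rose from 162 ± 101 to 10800 ± 1210 (adjusted p = 0.00733), and with the Hox score in the model its log2 difference of 5.79 ± 1.12 became 2.502 (adjusted p = 0.0587). In total 183 genes were higher and 243 lower (426 genes, 3.72% of those tested). Of 39 lists, 11 were called, 5 up and 6 down. The gene count was 187, 274 and 106 without human feces replicates 1, 2 and 3, and 261, 201 and 281 without mouse cecum replicates 1, 2 and 3. It was 130 with the Hox score in the model, where the median SE rose from 0.114 to 0.136, and 79 of the 426 genes were still called.

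Tongue recipients had lower transcripts of xenobiotic metabolism and transport, with 11 of 20 genes lower and 1 higher (12 and 1 adjusted over the list alone). Abcb1a, the drug efflux pump P-glycoprotein, fell from 13000 ± 873 to 5710 ± 219 (log2 -1.18 ± 0.14, adjusted p = 3.05e-05). The cytochrome Cyp2c55 fell from 25000 ± 2900 to 13900 ± 2820, Nqo1 from 1340 ± 5.98 to 704 ± 105, Gstm3 from 4140 ± 477 to 1930 ± 209 and Ces2a from 8600 ± 211 to 1410 ± 477. The list median was -0.65 (adjusted p = 7.66e-11, and 0.0025 with an estimated correlation). Cbr3, outside the list, fell to 1550 ± 101. S100g fell from 1290 ± 485 to 68.6 ± 54 and Arg2 from 1380 ± 76.5 to 277 ± 88.2.

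In the same mice macrophage and dendritic cell genes fell in 8 of 16 cases (10 adjusted over the list alone), among them the scavenger receptor Cd163 (396 ± 41 to 180 ± 18.8) and C1qc (to 805 ± 131), with a median of -0.41 (adjusted p = 8.18e-08, and adjusted p = 0.188 with an estimated correlation). Smooth muscle genes rose in 3 of 16 cases (5 adjusted over the list alone), including Pln, a regulator of the muscle calcium pump (576 ± 160 to 1040 ± 23.9). Their median was 0.16 (adjusted p = 0.000277, and adjusted p = 0.493 with an estimated correlation), and it was 0.093 without tongue replicate 3 and 0.261 and 0.095 without mouse cecum replicates 2 and 3. Genes of cytotoxic and intraepithelial lymphocytes fell in 2 of 7 cases (2 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.00693, and adjusted p = 0.446 with an estimated correlation). The call was lost with the Hox score in the model, although the median was then -0.392 (adjusted p = 0.0565). Hoxa9 rose from 520 ± 87.2 to 2530 ± 647 (log2 2.16 ± 0.28, adjusted p = 5.73e-05), Insl5 from 222 ± 17.4 to 1950 ± 1180 and Saa1 from 8080 ± 1250 to 21200 ± 4270. Reg3b fell from 12200 ± 4590 to 1650 ± 1060 (log2 -3.08 ± 0.65, adjusted p = 0.00619), and gave -1.615 with the Hox score in the model (adjusted p = 0.3). Neither the cell cycle list (median -0.07, adjusted p = 0.128) nor the E-box list (median 0.27, adjusted p = 0.0666) passed. In total 248 genes were higher and 305 lower (553 genes, 4.83% of those tested). Of 39 lists, 9 were called, 1 up and 8 down (14 without tongue replicate 3). The gene count was 319 and 354 without tongue replicates 2 and 3, and 321 and 322 without mouse cecum replicates 2 and 3. It was 178 with the Hox score in the model, where the median SE rose to 0.143, and 129 of the 553 genes were still called.

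Soil recipients had lower cell cycle transcripts than mouse cecum recipients, with 18 of 20 genes lower (18 adjusted over the list alone). Top2a fell from 2650 ± 215 to 1510 ± 91.2 (log2 -0.80 ± 0.09, adjusted p = 8.5e-05), the mitotic kinase Cdk1 from 1670 ± 192 to 1110 ± 28.3, the checkpoint kinase Bub1 from 420 ± 66.3 to 247 ± 15 and Mki67 from 2610 ± 137 to 1790 ± 103. The list median was -0.52 (adjusted p = 2.86e-21, and 0.0351 with an estimated correlation). Smooth muscle genes rose in 5 of 16 cases (12 adjusted over the list alone), among them the intermediate filament gene Des (5140 ± 821 to 7900 ± 1120) and Pln (576 ± 160 to 1040 ± 99.6). Their median was 0.37 (adjusted p = 1.32e-08, and adjusted p = 0.293 with an estimated correlation), or 0.239 without soil replicate 2. Reg4, a secreted lectin of the Reg family, fell from 12000 ± 8110 to 709 ± 178 (log2 -3.62 ± 0.5, adjusted p = 0.000213), and Reg3b from 12200 ± 4590 to 1630 ± 1250.

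E-box clock genes rose in 6 of 9 cases in soil recipients (7 adjusted over the list alone), with Dbp at 1180 ± 325 and a median of 0.62 (adjusted p = 1.01e-07, and 0.0304 with an estimated correlation). The Bmal1-phase list had 2 of 5 genes lower (2 adjusted over the list alone), including Npas2 (789 ± 103 to 456 ± 17.4), and a median of -0.18 (adjusted p = 0.0336, and adjusted p = 0.188 with an estimated correlation). That call was lost without soil replicates 1 and 3 (medians -0.149 and -0.058, adjusted p = 0.0582 and 0.0904) and mouse cecum replicate 3 (-0.043, adjusted p = 0.0631), and the median was -0.415 without soil replicate 2 and -0.377 without mouse cecum replicate 1. The xenobiotic list had 5 of 20 genes lower and 1 higher (7 and 1 adjusted over the list alone), with Nqo1 at 765 ± 40.1 and Akr1b8 at 2720 ± 115, and a median of -0.29 (adjusted p = 3.74e-06, and 0.0304 with an estimated correlation). Macrophage and dendritic cell genes fell in 4 of 16 cases (9 adjusted over the list alone), with Cd163 at 204 ± 47.2 and a median of -0.37 (adjusted p = 6.48e-07, and adjusted p = 0.237 with an estimated correlation). Genes of enteric neurons and glia rose in 1 of 13 cases (1 adjusted over the list alone, median 0.27, adjusted p = 0.0316, and adjusted p = 0.55 with an estimated correlation). This call was lost without mouse cecum replicate 3 (0.1, adjusted p = 0.456). Tuft cell genes rose in 1 of 7 cases (4 adjusted over the list alone, median 0.54, adjusted p = 0.00289, and adjusted p = 0.446 with an estimated correlation). The list call was lost without mouse cecum replicate 1 (0.183, adjusted p = 0.23). The list of cytotoxic and intraepithelial lymphocytes had a median of -0.39 (adjusted p = 0.0112, and adjusted p = 0.473 with an estimated correlation), with 0 of 7 genes past limma's threshold (2 adjusted over the list alone) and 2 at an unadjusted p under 0.05. Its call was lost without soil replicate 2 (-0.15, adjusted p = 0.163) or mouse cecum replicate 1 (adjusted p = 0.0629). The monoacylglycerol acyltransferase Mogat2 fell from 473 ± 122 to 164 ± 11 (log2 -1.26 ± 0.2, adjusted p = 0.000778). Mptx1 rose from 162 ± 101 to 15200 ± 13300 (log2 5.94 ± 1.12, adjusted p = 0.00328), Insl5 from 222 ± 17.4 to 1540 ± 971 and Hoxa9 from 520 ± 87.2 to 2260 ± 888. In total 250 genes were higher and 286 lower (536 genes, 4.68% of those tested). Of 39 lists, 11 were called, 4 up and 7 down. This gene count was 259 without soil replicate 2, and 329 and 263 without mouse cecum replicates 2 and 3.

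Termite hindgut recipients had higher Saa1 and Saa2 and lower xenobiotic transcripts than mouse cecum recipients. Saa1 and Saa2 were called higher, and Nqo1 lower, in all 7 comparisons, so these differences are not particular to this community. Saa2 rose from 357 ± 30 to 3020 ± 1260 (log2 2.84 ± 0.25, adjusted p = 2.38e-07) and Saa1 from 8080 ± 1250 to 28000 ± 3400. The antimicrobial and acute-phase list that holds both rose in 4 of 13 cases (4 higher and 2 lower adjusted over the list alone), with a median of 0.19 (adjusted p = 0.0131, and adjusted p = 0.111 with an estimated correlation). The call was lost without mouse cecum replicate 1 (adjusted p = 0.134). The median was 0.112, -0.038 and 0.348 without termite hindgut replicates 1, 2 and 3, and 0.387 without mouse cecum replicate 3. In the xenobiotic list 10 of 20 genes fell and 2 rose (12 and 5 adjusted over the list alone), with a median of -0.49 (adjusted p = 2.08e-05, and 0.0335 with an estimated correlation). Abcb1a fell from 13000 ± 873 to 5330 ± 1140, Akr1b8 from 5150 ± 631 to 2010 ± 293, Nqo1 from 1340 ± 5.98 to 621 ± 106 and Ces2a from 8600 ± 211 to 1150 ± 117. Cbr3 fell to 1160 ± 182 (log2 -1.70 ± 0.11, adjusted p = 1.39e-09). Slc7a9 rose from 581 ± 42.8 to 2350 ± 192, Slc34a2 from 450 ± 27.4 to 1480 ± 186 and the stearoyl-CoA desaturase Scd1 from 6300 ± 1240 to 18000 ± 2610. Small intestinal enterocyte genes rose in 4 of 9 cases (5 adjusted over the list alone), Enpep to 3960 ± 693, with a median of 0.80 (adjusted p = 0.000142, and 0.0426 with an estimated correlation), or 0.405 without termite hindgut replicate 1. The tight junction gene Cldn4 fell from 2140 ± 333 to 831 ± 223, Arg2 from 1380 ± 76.5 to 358 ± 142, and Sptssb, a subunit of the first enzyme of sphingolipid synthesis, from 11600 ± 891 to 3590 ± 1080.

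Genes of antigen presentation and of B cells were higher in termite hindgut recipients, but none of these list calls held with the Hox score in the model. MHC class I and interferon-gamma target genes rose in 1 of 16 cases (14 adjusted over the list alone), with a median of 0.59 (adjusted p = 3.09e-06, and adjusted p = 0.446 with an estimated correlation). The B cell list rose in 3 of 9 cases (9 adjusted over the list alone), with a median of 0.91 (adjusted p = 3.97e-05, and adjusted p = 0.446 with an estimated correlation), and the MHC class II list in 2 of 8 (8 adjusted over the list alone), with a median of 0.55 (adjusted p = 4.06e-05, and adjusted p = 0.384 with an estimated correlation). Without termite hindgut replicate 2 the B cell median was 0.496 and the MHC class I median 0.339, and without mouse cecum replicate 3 the latter was 0.393. With the Hox score in the model the medians of the MHC class I, B cell and MHC class II lists were 0.130, 0.174 and 0.115, and none passed (adjusted p = 0.226, 0.33 and 0.342).

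Lists of other cells moved in termite hindgut recipients as well. Plasma cell genes rose in 3 of 13 cases and fell in 1 (5 and 1 adjusted over the list alone), with a median of 0.36 (adjusted p = 0.0197, and adjusted p = 0.55 with an estimated correlation). Their call was lost without termite hindgut replicate 2 (0.233, adjusted p = 0.131), without mouse cecum replicate 1 (0.12) and with the Hox score in the model (0.3). Mature colonocyte genes rose in 3 of 17 cases (5 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.00578, and adjusted p = 0.409 with an estimated correlation). This list call was lost without mouse cecum replicate 1 (adjusted p = 0.0612) and with the Hox score in the model (0.003, adjusted p = 0.569). Adipocyte genes rose in 1 of 10 cases (1 adjusted over the list alone), with a median of 0.32 (adjusted p = 0.0408, and adjusted p = 0.679 with an estimated correlation). The call was lost without any 1 of the 3 termite hindgut mice (adjusted p = 0.0773, 0.0612 and 0.05) or mouse cecum replicate 3 (0.196, adjusted p = 0.133). Tgm3 rose from 104 ± 21.7 to 5900 ± 3030 and the peptide transporter Slc15a1 from 118 ± 47.3 to 1060 ± 528, and neither passed with the score (adjusted p = 0.199 and 0.258). Insl5 rose from 222 ± 17.4 to 2900 ± 609 (log2 3.42 ± 0.47, adjusted p = 8.68e-05) and passed with the score too (1.408, adjusted p = 0.00184). Cell cycle genes fell in 10 of 20 cases (15 adjusted over the list alone), with a median of -0.33 (adjusted p = 1.18e-07, and adjusted p = 0.3 with an estimated correlation). E-box clock genes rose in 1 of 9 cases (5 higher and 1 lower adjusted over the list alone), with a median of 0.36 (adjusted p = 0.0156, and adjusted p = 0.359 with an estimated correlation). Macrophage and dendritic cell genes did not shift as a list (median -0.01, adjusted p = 0.641), although 1 rose and 1 fell. In total 519 genes were higher and 661 lower (1180 genes, 10.3% of those tested). Of 39 lists, 18 were called, 12 up and 6 down. The gene count was 2057, 451 and 722 without termite hindgut replicates 1, 2 and 3, and 736 and 514 without mouse cecum replicates 2 and 3. It was 134 with the Hox score in the model, where the median SE rose to 0.155, and 108 of the 1180 genes were still called.

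**Figure D4:**
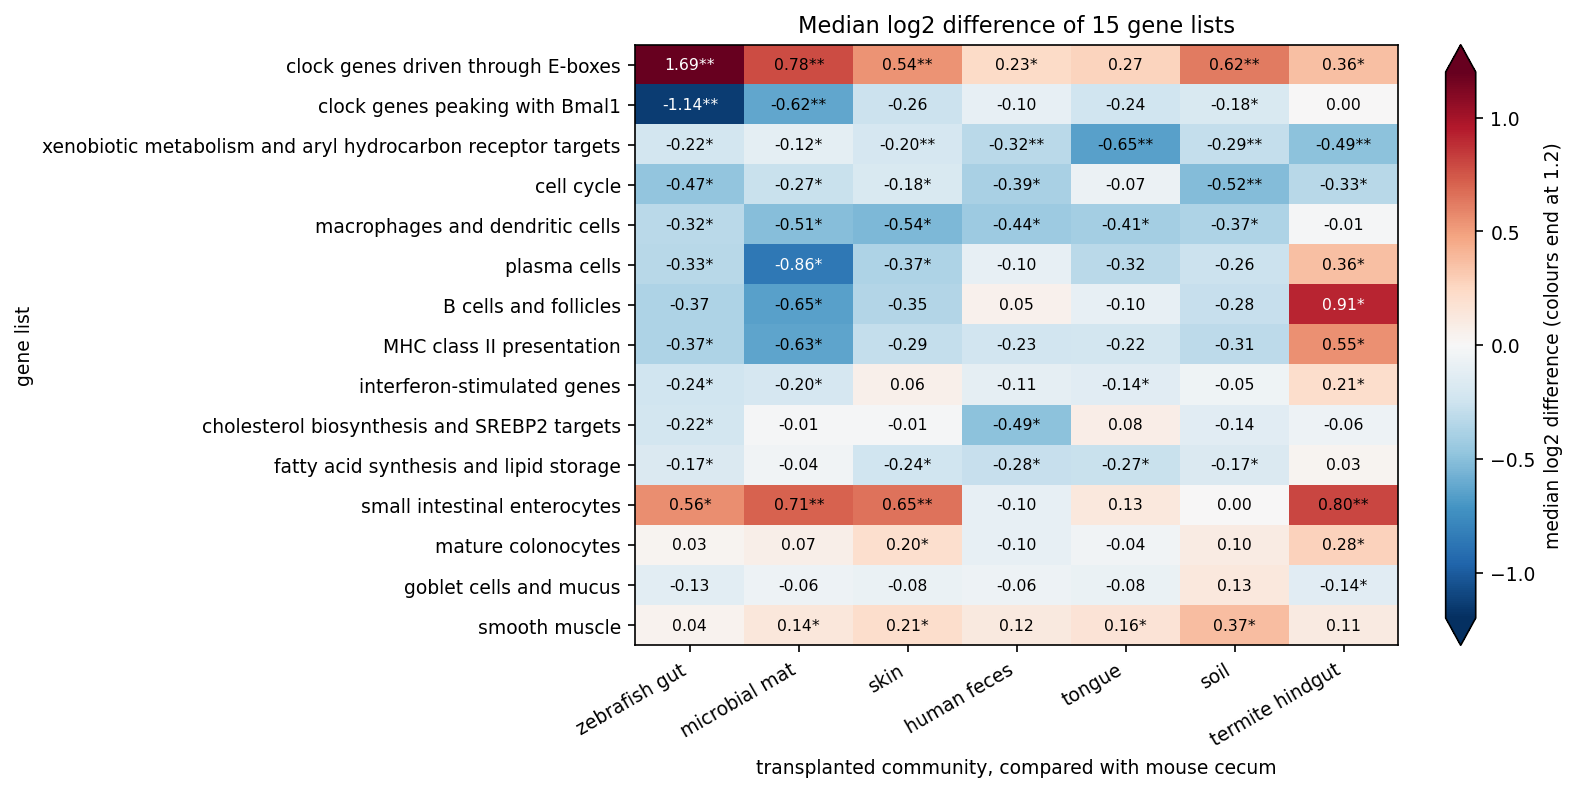
Median log2 difference from mouse cecum recipients for 15 gene lists (rows) and 7 communities (columns), with red for higher and blue for lower. A single asterisk marks a list called by camera with the preset correlation and a double asterisk one that also holds with an estimated correlation, such as the E-box clock list in zebrafish gut recipients at 1.69.

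Across the 7 comparisons, 96 list calls were made among 273 list tests, and 15 held with an estimated correlation. These were the E-box clock list in zebrafish gut, microbial mat, skin and soil recipients, the Bmal1-phase list in zebrafish gut and microbial mat recipients, and the xenobiotic list in skin, human feces, tongue, soil and termite hindgut recipients. The small intestinal enterocyte list in microbial mat, skin and termite hindgut recipients and the cell cycle list in soil recipients completed them. In the mat recipients the xenobiotic list had 6 of 20 genes lower and 2 higher (8 and 4 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.0257, and adjusted p = 0.304 with an estimated correlation). That median was -0.201 and -0.069 without microbial mat replicates 1 and 2, and the call was lost without mouse cecum replicate 3 (adjusted p = 0.0525). The call was also lost, at medians close to the main one, after quantile normalization (-0.119, adjusted p = 0.0706) and with the Hox score in the model (-0.111, adjusted p = 0.0916). The lists for T cells, neutrophils, mast cells, Paneth cells and erythrocytes had fewer than 5 tested genes and were not tested.

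Some genes were called in all 7 comparisons, 7 higher and 22 lower than in mouse cecum recipients. Saa1 and Saa2 were among the higher genes and Gstm3, Nqo1, Cbr3, Arg2, Slc30a10, Sprr1a and Ccl8 among the lower ones, beside the lipid-sensing receptor Pparg and the glutathione transferase Gstp1, which were singled out after their values were seen. In human feces recipients the Saa1 call was lost without replicate 3 (adjusted p = 0.0561) and the Saa2 call without replicates 1 and 3 (0.103 and 0.214) or mouse cecum replicates 1, 2 and 3 (0.0746, 0.124 and 0.0689), and also with a constant of 200 (0.0609), without a filter (0.0575), with a robust fit (0.0537) and with only the groups compared (0.055). With the Hox score in the model, Saa1 (0.0966), Saa2 (0.411) and Nqo1 (0.105) did not pass there, and Cbr3 lay at the threshold. The Cbr3 call was lost in microbial mat recipients without replicate 2 (0.0665) or mouse cecum replicate 3 (0.0706), and in zebrafish gut recipients without replicate 3 (0.0534). In all, 2308 genes were called in at least 1 comparison, 929 in 2 or more, and 24 in opposite directions in different comparisons. All 7 comparisons share the same 3 mouse cecum arrays. In 20 simulations all 24 arrays, mouse cecum included, were drawn as independent noise around each gene's mean. The mean correlation of log2 differences between comparisons was 0.498 in them, against 0.61 observed over the 21 pairs. The mean covariance was 0.011 against 0.0405, a difference of 0.0295. Those simulations gave 0 genes called in 2 or more comparisons by limma. They hold no trait of the real mouse cecum mice, so they cannot show how much these mice contribute. A pair of comparisons shared 87.9 higher and 119.7 lower calls on average, where independent lists of the same sizes would share 7 and 10. The 3 control arrays are too few to split, and part of the excess may come from sharing them.

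No gene separated the gut-derived communities (mouse cecum, human feces, zebrafish gut and termite hindgut) from the non-gut communities (microbial mat, skin, tongue and soil). With the 8 community means as units, limma called 0 genes, 504 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.989. The B-lineage transcription factor Ebf1 had the smallest p among genes higher after gut-derived communities (log2 difference 0.33 ± 0.07, limma adjusted p = 0.989), and the palmitoyltransferase Zdhhc20 among those lower (-0.32 ± 0.07, adjusted p = 0.989), and neither passed. Camera called 13 lists with the preset correlation, among them macrophage and dendritic cell genes (median 0.28, adjusted p = 1.03e-08) and smooth muscle genes (median -0.18, adjusted p = 1.03e-08). With an estimated correlation camera called 0, with 3 lists at an unadjusted p under 0.05, and the macrophage and smooth muscle lists had adjusted p = 0.531 and 0.48. With the 24 mice as units, which counts mice of the same community as independent, 329 genes passed.

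Several genes known to respond to microbes were followed whatever their test. Cyp1a1 differed among the 8 groups and moved in both directions against the 331 ± 48.9 of mouse cecum recipients. It passed upward in zebrafish gut recipients and tongue recipients (734 ± 49, adjusted p = 0.0134) and downward in termite hindgut recipients (149 ± 57, adjusted p = 0.0149). The tongue call was lost without mouse cecum replicate 2 (adjusted p = 0.0589) and the termite hindgut call without termite hindgut replicate 2 (0.088) or mouse cecum replicate 3 (0.0789). With the Hox score in the model neither passed, though both kept their direction, at log2 differences of 0.909 and -1.131 (adjusted p = 0.191 and 0.126). The mucin gene Muc2 (F-test adjusted p = 0.135), the goblet cell product Retnlb (0.0682) and the antimicrobial ribonuclease Ang4 (0.0512) did not pass the test over all groups. Ang4 had a signal of 13800 ± 11600 in mouse cecum recipients, a spread nearly as large as its mean. Nos2 and Mcpt1 fell below the signal filter and were not tested.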

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

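The lists and genes tested here for a community standing apart were chosen after the comparison of gut-derived with non-gut communities had singled them out. For 38 groups of 4 communities (gut-derived or non-gut), the community with the highest or lowest mean was set against the range of all 4 by Dixon's ratio, which chance passes in about 1 of 20 groups. The MHC class II list had a mean log2 signal of 10.38 in microbial mat recipients, below the 10.67 to 10.72 of the other non-gut communities (ratio 0.845). Pcdh17, a protocadherin, had a mean log2 signal of 9.4 in microbial mat recipients, above the 8.88 to 8.97 of the other non-gut communities, with a ratio just over the critical value. The pancreatic acinar list had a mean of 8.4 in termite hindgut recipients, above the 6.88 to 6.91 of the other gut-derived communities (ratio 0.98). Against mouse cecum its median difference was 2.01 (camera adjusted p = 0.0248, and adjusted p = 0.671 with an estimated correlation). By limma 0 of 7 genes passed (0 adjusted over the list alone), with 4 at an unadjusted p under 0.05. The median was -0.114 without termite hindgut replicate 3 (adjusted p = 0.713), and the call was lost without mouse cecum replicate 1 (2.073, adjusted p = 0.0629).

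Probe sets that the annotation used here does not name also differed from mouse cecum recipients. Of 2276 such probe sets above the filter, 59 were higher and 35 lower in zebrafish gut recipients, 24 and 25 in microbial mat recipients, 44 and 28 in skin recipients, 24 and 21 in human feces recipients, 26 and 32 in tongue recipients, 27 and 22 in soil recipients, and 73 and 66 in termite hindgut recipients. Their genes were not identified here.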

How the results depend on the processing

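The fit with the Hox score was chosen only after the data had been seen, and the other alternatives were planned. Over the 382 called named-gene results, the call and direction held for 378 with a constant of 1, 375 with 200, 373 with median scaling, 369 with quantile normalization, 368 with the replicate block, 364 with all probe sets, 356 with a robust fit, 329 without a filter, 296 with only the groups compared, 252 with the Hox score and all 317 still tested under the stricter filter. Leaving out an array ended 539 of 2292 such calls. Of 96 list calls, 96 held with a constant of 1, 95 without a filter, 91 with quantile normalization, 79 with the Hox score and 15 with estimated correlations. Leaving out an array ended 71 and reversed 1 of 576.

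Leaving out each array in turn gave 271 to 652 genes for zebrafish gut, 163 to 396 for microbial mat, 256 to 601 for skin, 106 to 281 for human feces, 319 to 533 for tongue, 259 to 568 for soil, 451 to 2057 for termite hindgut and 1643 to 3307 for the F-test. Leaving out each community in turn gave 0 genes by limma for gut-derived against non-gut, as all 8 communities did, with 504 genes at an unadjusted p under 0.05 over all 8. Lists called ranged from 13 to 18, 11 to 20, 11 to 15, 8 to 14, 8 to 14, 10 to 16 and 14 to 19 in the same order of communities. With all probe sets more features were tested, and 1136 (zebrafish gut, 584 higher and 552 lower), 908 (skin, 477 and 431), 926 (tongue, 503 and 423) and 3997 (F-test) passed. With only the groups compared, 304 passed for skin, 246 for human feces, 277 for tongue, 241 for soil and 360 (200 higher, 160 lower) for termite hindgut, but 782 for zebrafish gut and 518 for microbial mat. With the Hox score 130 passed for human feces, 178 for tongue, 134 (74 higher, 60 lower) for termite hindgut, 485 for skin and 361 for soil, but 943 for zebrafish gut and 447 for microbial mat, and 19 and 20 lists for human feces and soil. With 24 mice as units, which counts mice of the same community as independent, 329 genes passed for gut-derived against non-gut communities. With estimated correlations 2, 3, 3, 1, 1, 3 and 2 lists held in the order above, and camera called 0 for gut-derived against non-gut, with 3 at an unadjusted p under 0.05.

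The Hox score reversed Car4 in human feces (-0.469) and tongue (-0.446) recipients and Aqp8 in tongue (-2.443) and termite hindgut (-2.418) recipients, none of them called before. In termite hindgut recipients the estimates of Atp12a (-0.845), Hoxb13 (-0.311, limma adjusted p = 0.837), Pou2af1 (-0.020) and Wfdc2 (-0.125) changed sign with the score. Hoxb13 dominates the score, so its change follows from how the score was built. The camera call of the bile acid list in tongue recipients was lost with a change of direction (0.1, adjusted p = 0.87). So were those of the plasma cell (-0.053, 0.3) and interferon-stimulated (-0.041, 0.646) lists in termite hindgut recipients. After quantile normalization the oxidative phosphorylation list in tongue recipients lost its call and its camera direction turned (median -0.027, adjusted p = 0.911). The pancreatic acinar list in termite hindgut recipients ran from -0.114 (without replicate 3) to 2.982 with an array left out. The cause of these changes, Hoxb13 apart, and of the moved counts above except with all probe sets, was not tested. The replicate numbers did not pair the mice, since deviations of same-numbered arrays correlated at -0.34 to 0.4 (median 0), with 22 of 84 pairs over 0.1 and 9 of 24 arrays closest to their own number. With the number as a block 658, 390, 567, 407, 524, 504 and 1115 genes passed. Weak signals limit what can be seen, since genes with a mean signal under 120.4 were not tested.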

Other observations

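The test of the clock lists against each other, the test of Hoxb13 against other Hox genes and the tests with the Hox score were chosen only after the results were seen, and mouse cecum replicate 1 was singled out after its values were seen. Some secreted products had low signals in that mouse, and others such as Muc2 (20600, against 25680 and 22050) did not stand apart. Replicate 1 had a signal of 422.2 for Ang4, 2555 for the resistin-like Retnlb, 2708 for Reg4 and 44.5 for the lectin Itln1, while replicates 2 and 3 had 20340 and 20770 (Ang4), 19050 and 16260 (Retnlb), 16210 and 17230 (Reg4), and 532.2 and 427.1 (Itln1). The same mouse had the highest mouse cecum signals of the interferon-stimulated genes Ifit1 (1394, against 599.5 and 539.4) and Rsad2 (1537, against 886.8 and 768.3). The interferon-stimulated list fell in zebrafish gut recipients in 5 of 20 cases (5 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.00892, and adjusted p = 0.679 with an estimated correlation), and had a median of -0.024 without that array (adjusted p = 0.432).

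Goblet cell genes fell in termite hindgut recipients in 6 of 17 cases (7 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.0127, and adjusted p = 0.533 with an estimated correlation), or -0.086 without termite hindgut replicate 2 and -0.22 without mouse cecum replicate 3. Spink4, a secreted goblet cell peptide, fell from 21900 ± 4840 to 12100 ± 1420 and the transcription factor Gfi1 from 447 ± 48.3 to 238 ± 48.8. With the Hox score in the model neither passed, at log2 differences of -0.84 and -0.588 (adjusted p = 0.0828 and 0.281). The median SE over genes was also larger in that fit, at 0.155 against 0.114. The cytochrome Cyp2d26 was higher in 5 of the 7 comparisons with mouse cecum, while Nqo1 and Gstm3 of the same list were lower in all 7, or in 5 (Nqo1) and 7 (Gstm3) with the Hox score in the model.

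The E-box clock list was called higher in zebrafish gut, microbial mat, skin, human feces, soil and termite hindgut recipients (for human feces and termite hindgut adjusted p = 0.188 and 0.359 with an estimated correlation), with a mean shift of 0.643 over all 7 groups. With the Hox score in the model 108% of that shift was kept. As far as the score tracks position, this argued against a different stretch of colon as the whole cause. Zebrafish gut recipients had the largest shift and scores close to those of mouse cecum recipients, so the score could not lower their shift. In the groups with the highest scores, the medians without and with the score were 0.36 and 0.37 (termite hindgut), 0.23 and 0.39 (human feces) and 0.27 and 0.39 (tongue). A different circadian time at death may contribute, because it would move the Bmal1-phase list opposite to the E-box list. Over the 7 groups the list medians had a Spearman rho of -0.75 (exact two-sided p = 0.0663) and a Pearson r of -0.943 (exact p = 0.00675), or -0.719 without the 2 farthest groups. Simulated unchanged groups gave a median rho of 0, but their genes were drawn independently, so that value was built in. The relation of the list medians was the 1 such relation computed, and it misses the threshold by rho. The time of death is not given in the sources used here, and a direct effect of the community on the clock stays open and untested.

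The higher Hox genes of the distal colon may reflect a different stretch of colon. Across within-group deviations of the 24 arrays Hoxb13 ran opposite to Hoxb6 (r = -0.535, permutation p = 0.0304, adjusted 0.0406 over 4 relations, rho = -0.496, p = 0.0381) and Hoxd10 (r = -0.551, p = 0.0171, adjusted 0.0343, rho = -0.5, p = 0.0555). Without the 2 farthest arrays these were -0.367 and -0.53, so the relation with Hoxb6 rests in part on them. Both genes had the most negative loadings on the Hox score (-0.145 and -0.162), against 0.836 for Hoxb13. The score came from the same arrays, so opposite signs were partly built in. The permutation p-values therefore give no independent evidence for a different stretch of colon. A different amount of epithelium stays open too, because the Hox score rose with the mature colonocyte list (r = 0.831, permutation p = 0.00021, adjusted 0.00084, rho = 0.769, p = 0.00018, and 0.741 without the 2 farthest), while for smooth muscle r was 0.196 (permutation p = 0.425, rho = 0.0965, p = 0.678, and 0.172 without them). These genes also mark position, so the tests do not rank the explanations. An effect of the community on Hox expression was not tested.

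Genes of the xenobiotic metabolism list fell past the threshold in 52 cases over the 7 comparisons. With the Hox score in the model 69.2% of these falls were kept. That share pools all 7 comparisons and was not computed by group. Zebrafish gut recipients had scores close to those of mouse cecum recipients, so the score could not remove their 8 falls. As far as the score tracks position, these 8 argued against a different stretch of colon as the whole cause in zebrafish gut recipients. In the other groups the pooled share cannot decide this, and a different stretch of colon stays open. By gene, the comparisons with a fall numbered 7 without and 7 with the score for Gstm3, and 6 and 6 for Akr1b8. They numbered 4 and 0 for Ces1g, and 3 and 0 for Gsta4. Array scaling was argued against by 96.2% kept after quantile normalization, and a single aberrant mouse cecum array by 78.8% to 80.8% kept when each of the 3 was left out. Differences between isolators and a change in the mix of cells in the tissue stay open, and no test separated them from the pattern. An effect of the community stays open too, as a hypothesis found and tested on the same data.

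For the counts of called genes, the 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of 10 as large in each case, gave 723, 414, 571, 426, 553, 536 and 1180 genes for zebrafish gut, microbial mat, skin, human feces, tongue, soil and termite hindgut, and the highest other split gave 1, 1, 2, 4, 3, 3 and 3. Every other split mixes both groups, so its low count follows from any difference between them, isolators included. For the F-test, 1 of 100 regroupings, the real one, gave 2342 genes and the highest other 111, so random placement of single mice was excluded at that share. The regroupings treat mice as separate units, so they cannot exclude differences between isolators. For gut-derived against non-gut communities the real split gave 0 genes by limma (504 at an unadjusted p under 0.05) and the highest other gave 9. A count of 0 is reached by all 35 of 35 splits whatever the data, so these splits say nothing about chance.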
